A study of Arabidopsis thaliana with 7 samples.

How the data were processed

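Roots of 6-day-old Arabidopsis thaliana seedlings were measured in 7 libraries. The single-cell libraries were made with 10x Genomics 3' chemistry from cells freed by 2 h of wall digestion: 2 of wild type (Col-0, and Col-0 with an endodermal GFP reporter) and 1 of shr-3, a SHORT-ROOT knockout in a mixed Col-0 and Ler background. The bulk libraries were poly(A)-selected and strand-specific, 2 from protoplasted and 2 from unprotoplasted roots. The labels name Cell Ranger 2.0.2, Trimmomatic 0.36, STAR (version not stated), HTSeq 0.7.2 and the TAIR10 genome, and do not state the strand setting of the counting. The deposited single-cell values were UMI counts per gene and cell, with no normalization. The deposited bulk values were read counts per gene, with RPM columns (reads scaled to equal library size) computed by the authors beside them. The RPM columns were used only to check their divisor, which was 1.02 to 1.04 times the sum of the listed counts. Of 27628 loci, 27420 matched the reference annotation.

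The series states 5767 cells, and the matrices hold 5826 barcodes, 59 more. Each wild-type replicate was loaded with 12200 cells. The wild-type matrix holds barcode suffixes 1 and 2, which no label ties to a replicate, so values are given per suffix and without replicate numbers. Total UMIs were 72947836 for suffix 1, 66324602 for suffix 2 and 20294416 for shr-3, and bulk totals ran from 12116926 to 19829769 counts. No cell was removed. A doublet caller was tried and called 4 of 5826 cells, far too few for such a load, so its calls were not used. In its place, results were recomputed without cells over 4 times their own library's median UMIs, 593 of 4727 wild-type and 163 of 1099 shr-3 cells.

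Bulk counts were tested in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr and the quasi-likelihood F test on a design of condition alone, two-sided, with Benjamini-Hochberg adjustment over 19641 genes. The TMM factors were 0.879 and 0.860 in protoplasted and 1.14 and 1.16 in unprotoplasted libraries, and the common biological coefficient of variation was 0.176. Replicate 1 deviations of the conditions correlated at -0.0221, so replicate numbers do not pair the samples. The 27 gene lists, written before the data were examined, were tested with camera in limma 3.58.1 (preset correlation 0.01, voom weights), adjusted over the lists by Benjamini-Hochberg, and again with an estimated correlation. They were also tested with fry, which compares a list with no other genes, so its p is not part of the camera ranges. In camera, direction is that of the list against all other genes. Mean and SD of CPM use TMM-scaled library sizes. A fold against 0 counts was taken against a floor of 3 counts over the group, and 1 to 3 counts are given as a ratio with its counting interval. These p-values measure the spread between 2 libraries per condition, which may be technical. Intervals and floors cover counting error only, and bulk reads without molecular identifiers are not independent molecules.

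In simulated data with this spread, 100 of 19641 genes were changed 2-fold and 100 were changed 4-fold. The bulk test recovered 39% and 92% of them. It made 20 false calls among 151, a higher share than an adjusted p under 0.05 aims at. In the real data 5165 genes rose and 5048 fell. Recovery depends on how many genes change, so these values do not give the sensitivity of the reported test.

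Single cells were summed per genotype and suffix and given as CPM (UMIs scaled to equal totals) with exact Poisson 95% intervals. Log2 ratios of shr-3 over wild type add 0.5 to each sum. For each list the median ratio was set against 10000 random lists of the same size matched on expression in 20 bins, and its counting interval came from 1000 Poisson resamples. As a check, random lists of 15 genes were drawn from the real ratios. Of these, 50 of 50 lists raised 4-fold lay above the random range and 1 of 50 unchanged lists lay outside it. Random genes need not vary together as list members may, so this does not give the rate of false calls for the real lists. For cell classes, all cells were scaled to 10000 UMIs, log-transformed and clustered together in scanpy 1.11.5 (Python 3.11.15, igraph 0.11.9; 2000 variable genes, 50 principal components, 15 neighbours, Leiden resolution 1, seed 0), which gave 29 clusters. A cluster took a name when at least 3 markers of a class were raised 2-fold and seen in 10% of its cells with a mean log2 fold of at least 1. It stayed unnamed where its top 10 genes held more markers of another class, or where its median UMIs were under 0.333 of its library's median with no own marker among its top 10. The minimum of 1 was kept as the main setting and 0.5 was tried after seeing the data. Names end in -like, since they rest on marker transcripts. Shares carry exact binomial (Clopper-Pearson) 95% intervals, and the limit given beside 0 cells is 3 counts of the total, which is not that interval. Root hair-like cells were ordered by diffusion pseudotime.

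Named genes follow a rule written before the data were examined. For bulk these are the 10 highest and 10 lowest log2 fold changes among genes past the test with a mean log2 CPM of at least 5 and no overlap between conditions, and the 4 members of each list with the lowest adjusted p, with others for contrast. For single cells these are SHR and its downstream genes, the 10 highest and 10 lowest ratios among genes with at least 50 CPM in 1 genotype and 100 UMIs, the 4 members of each list with most UMIs, and the root hair markers. Some genes that this rule selects are not reported here.

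Alternatives for bulk were DESeq2 size factors in edgeR, library size alone, no filter, a filter of 1 CPM in all 4 libraries, each library left out, replicate number as a block, DESeq2 1.42.0 and limma-voom. For single cells they were a TMM factor, every cell weighted alike, cells with at least 5000 UMIs, each suffix alone, list members with at least 10 UMIs, Leiden resolutions 0.5 and 2, clustering without genes changed by protoplasting, each genotype alone, 30 neighbours, and a pseudocount of 0.1 or a minimum of 1 CPM for the correlations. Chosen after seeing the data were the score of 0.5, clustering without genes 4-fold apart between the genotypes, and leaving out photosynthetic-like cells or the cells of very high UMIs.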

Results

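Gene expression was measured in roots of 6-day-old Arabidopsis thaliana seedlings by droplet single-cell RNA sequencing and by bulk RNA sequencing. The 7 libraries form 4 groups: 2 wild-type single-cell libraries, 1 single-cell library of shr-3, a knockout of the transcription factor gene SHORT-ROOT (SHR), 2 bulk libraries of unprotoplasted roots and 2 of protoplasted roots. Protoplasts are cells freed from their walls, here by 2 h of enzyme digestion. The wild-type cells numbered 4727 and held 139272438 UMIs (unique molecular identifiers, 1 per captured transcript), with a median of 14754 per cell. Of these, 2367 cells with 72947836 UMIs carried barcode suffix 1 and 2360 cells with 66324602 UMIs carried suffix 2. No label ties a suffix to a replicate, so the wild-type libraries are called suffix 1 and suffix 2. The shr-3 library held 1099 cells and 20294416 UMIs, with a lower median of 8201 per cell. The reads counted in genes numbered 13413641 and 12116926 in protoplasted replicates 1 and 2, and 19829769 and 15571204 in unprotoplasted replicates 1 and 2.

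The bulk libraries address which transcripts change when roots are turned into protoplasts. Genes of jasmonate and wounding, heat shock, and early stress signalling rose together, and genes of suberin synthesis, iron uptake, cell division and the endodermis fell. With an estimated correlation among list members, in place of a preset one, the adjusted p of these lists was between 0.22 and 0.368, so none of these list calls held with it. That setting rests on the few residual degrees of freedom of 4 libraries, so this loss does not show that correlation undoes the calls. With fry, which compares a list with no other genes, their adjusted p was between 0.00238 and 0.0282. LOX3 (AT1G17420), a lipoxygenase of jasmonate synthesis, had 148.5 ± 24.3 CPM (counts scaled to equal library size, mean ± SD, n = 2) in protoplasted roots and 1 count in unprotoplasted roots, a ratio of 6082 with a 95% counting interval of 1091 to 240280. CYP86A1 (AT5G58860), a fatty acid hydroxylase of suberin synthesis, had 0 counts in protoplasted roots and 120.2 ± 25.5 CPM (n = 2) in unprotoplasted roots, so it was at least 874-fold lower against a floor of 3 counts over the group. CYP86A1 lies on chromosome 5 of the TAIR10 build, from 23765791 to 23768111. At an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg) and at least 2-fold, 3716 of 19641 tested genes rose and 3062 fell. At any fold, 5165 rose and 5048 fell, and this call is used for the list members named here. Scaled by library size alone, 3706 rose and 8311 fell at any fold. The protoplasted and unprotoplasted libraries did not overlap for 79.5% of the tested genes, where chance gives 33.3%.

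**Figure D1:**
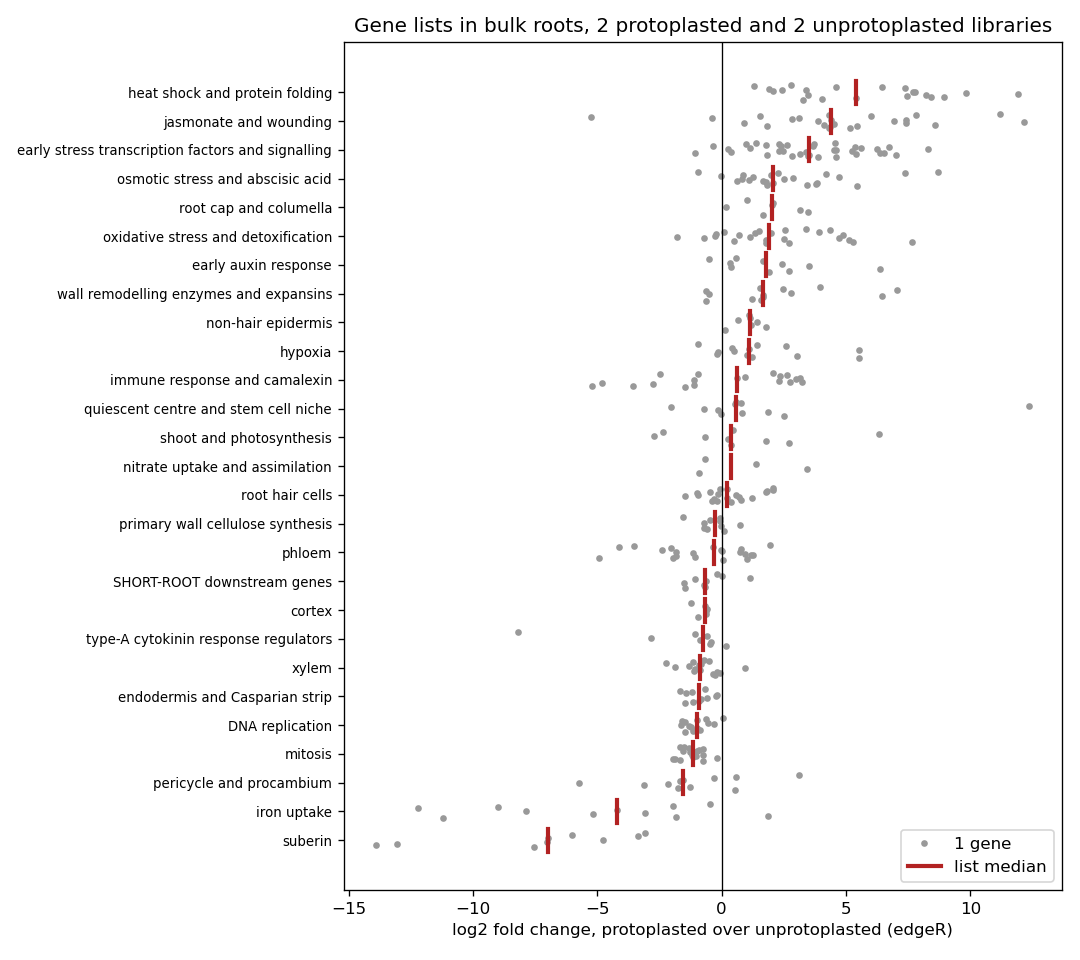
Log2 fold change of each tested member of the 27 gene lists, protoplasted over unprotoplasted bulk roots (n = 2 each), with 1 point per gene and a bar at each list's median. The heat shock list has the median of 5.41 and the suberin list that of -6.97.

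Jasmonate and wounding genes rose in 22 of 24 tested members (camera adjusted p = 2.86e-11), heat shock and protein folding genes in 21 of 21 (8.31e-13), and early stress transcription factors and signalling genes in 32 of 36 (3.65e-13). For these lists the adjusted p was 0.22, 0.255 and 0.22 with an estimated correlation, the highest over the alternatives. JAZ10 and JAZ9, repressors of jasmonate signalling, rose by a log2 fold of 7.40 ± 0.23 and 4.53 ± 0.17 (± SE), and ORA47, an activator of jasmonate synthesis genes, by 7.81 ± 0.28. VSP1, a vegetative storage protein gene that jasmonate induces in shoots, was the 1 member that fell, with a log2 fold of -5.27. Among heat shock genes, the small chaperones HSP17.6II, HSP17.6A and HSP17.6C rose by 8.94, 8.43 and 8.23, and DREB2A, a dehydration and heat regulator, by 7.37. WRKY40 and WRKY46, transcription factors of the wound and pathogen response, rose by 7.00 and 6.38, ERF6 by 4.52, and ACS6, an enzyme of ethylene synthesis, by 4.55, while WRKY70 fell with -1.07. Osmotic stress and abscisic acid genes rose in 20 of 23 members (camera adjusted p = 2.12e-07) and oxidative stress and detoxification genes in 18 of 24, with 1 fallen (4.66e-06). Their adjusted p was 0.36 and 0.332 with an estimated correlation. GOLS2, a galactinol synthase, rose by 8.70, LEA7, a late embryogenesis abundant protein gene, by 7.37 and RD29A by 5.44. The glutathione transferase gene GSTU25 reached 2802 ± 970 CPM from 106.3 ± 16.4 CPM, and OPR1 reached 5480 ± 1082 CPM from 265.9 ± 95.9 CPM.

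Hypoxia genes rose in 8 of 13 members and fell in 1 (camera adjusted p = 0.011), wall remodelling enzymes and expansins rose in 10 of 13 and fell in 1 (0.00346), early auxin response genes rose in 6 of 10 (0.00271) and root cap and columella genes in 5 of 7 (0.00346). In each of these 4 lists the adjusted p was 0.255 with an estimated correlation. ADH1, alcohol dehydrogenase, rose by 5.53 ± 0.49 (log2 fold ± SE) and HRE2, a hypoxia-responsive factor, by 5.52 ± 0.44. XTH22, a touch-induced xyloglucan hydrolase, rose by 6.43, EXPA1, an expansin, by 2.78, and the auxin-induced repressor genes IAA19 and IAA2 by 3.53 and 2.71. BRN1, BRN2 and SMB, transcription factors of root cap maturation, rose by 3.47, 3.16 and 1.67. Non-hair epidermis genes rose in 5 of 7 members (camera adjusted p = 0.0215), among them CPC by 1.80 and TTG2 by 1.18. That list had an adjusted p of 0.287 with an estimated correlation, 0.0953 without unprotoplasted replicate 1 and 0.112 without unprotoplasted replicate 2, with 0.287 the highest over the alternatives. The 10 highest changes among genes of at least 5 mean log2 CPM were those of BHLH92, AT4G33930, LOX3, FAMT, AT1G71000, ERF109, AT5G61890, TAT3, DDF1 and ABR1. BHLH92 had 78.6 ± 2.30 CPM in protoplasted roots and 0 counts in unprotoplasted roots, at least 1064-fold higher. FAMT, a farnesoic acid methyltransferase, rose by 11.32, ERF109, a wound-induced ethylene response factor, by 11.19, TAT3, a tyrosine aminotransferase, by 10.84 and ABR1 by 10.51.

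All 9 suberin genes fell (camera adjusted p = 1.59e-06), with a median log2 fold of -6.97. Endodermis and Casparian strip genes fell in 9 of 11 members (0.00056), mitosis genes in 18 of 19 (1.46e-05) and pericycle and procambium genes in 7 of 11, with 1 risen (0.011). In each of these 4 lists the adjusted p was 0.255 with an estimated correlation. CYP86B1, a further suberin hydroxylase, was at least 502-fold lower, GPAT5, a glycerol phosphate acyltransferase, fell by 7.53 and ABCG6, a suberin transporter, fell by 6.00. Casparian strip genes fell less: CASP1, a strip scaffold protein gene, fell by 1.17 ± 0.16 (log2 fold ± SE), PER64, its peroxidase, fell by 1.44 ± 0.15, and SCR fell by 1.48 ± 0.16. The mitotic cyclin genes CYCB1;4 and CYCB1;2 fell by 1.97 and 1.68, and the kinesin gene HIK fell by 1.52. NPF7.3, PHO1 and SKOR, which load nitrate, phosphate and potassium into the xylem, fell by 5.75, 3.11 and 2.16, while MP, an auxin response factor gene, rose by 3.13. DNA replication genes fell in 12 of 15 members (camera adjusted p = 0.000397) and xylem genes in 7 of 16, with 1 risen (0.00455). Their adjusted p was 0.368 and 0.36 with an estimated correlation. PCNA2 and RNR1 fell by 1.62 and 1.60, ACL5, a thermospermine synthase of xylem, fell by 2.22 and LAC4, a lignin laccase, fell by 1.87.

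Iron uptake genes fell in 9 of 11 members (camera adjusted p = 0.00147, or 0.311 with an estimated correlation), with a median log2 fold of -4.21, or -3.75 with genes at 0 counts set to their bounds. The other 26 lists had the same median to 2 decimals with such bounds. IRT1 (AT4G19690), the main root iron transporter, had 2 counts in protoplasted roots and 230.7 ± 16.0 CPM (n = 2) in unprotoplasted roots, a ratio of 0.000393 with a counting interval of 4.76e-05 to 0.00142. CYP82C4, of coumarin synthesis, was at least 281-fold lower, and FIT, the regulator of IRT1, was the 1 member that rose, by 1.85. Type-A cytokinin response regulators fell in 5 of 8 members (camera adjusted p = 0.0164), with ARR7 at -2.83 and ARR9 at -1.09. The adjusted p of the cytokinin list was 0.386 with an estimated correlation, and that of the iron and cytokinin lists was 0.239 and 0.0948 with a stricter filter of 1 CPM in all 4 libraries. The call of the cytokinin list was also lost without unprotoplasted replicate 1, which left 1 library in that condition. Beside CYP86A1, CYP86B1 and IRT1, the 10 lowest changes were those of AT1G26390, NAS1, AT1G55990, AT5G37690, MLP328, AT2G23540 and PELPK1. NAS1, a nicotianamine synthase, was at least 481-fold lower, MLP328 fell by 9.43 and PELPK1, of the cell wall, fell by 9.09. AT1G26390 was at least 505-fold lower, but its unprotoplasted level differed between replicates, at 74.6 ± 77.5 CPM (n = 2).

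In 9 lists the camera test did not pass. Phloem genes rose in 6 of 21 members and fell in 10 (adjusted p = 0.331), with BAM3, a receptor kinase, at -2.41, SEOR2, a sieve element protein gene, at -4.93 and BZIP6 at 1.95. Root hair genes rose in 6 of 20 and fell in 3 (0.283), with ROPGEF3 at 2.07 and RBOHC at 2.05. Immune response and camalexin genes rose in 9 of 19 and fell in 6 (0.427), with PEPR1, a danger peptide receptor, at 3.24 and CYP79B3, of indole glucosinolate and camalexin synthesis, at -4.79. That list had a median of 0.60, a mean of -0.02 and a test direction of up. SHORT-ROOT downstream genes rose in 1 of 9 and fell in 5 (0.0857), with JKD at -1.50. Stem cell niche genes rose in 3 of 11 and fell in 1 (0.256). ERF115, a regulator of division after wounding, had 0 counts in unprotoplasted roots and was at least 560.1-fold higher in protoplasted roots, while BRAVO had -2.03. Cortex genes rose in 0 of 6 and fell in 2 (0.0947), cellulose synthesis genes rose in 1 of 10 and fell in 3 (0.178), with CTL2 at -1.54, and nitrate genes rose in 2 of 4 and fell in 2 (0.742), with NIA1, a nitrate reductase, at 3.42. NIA1 differed between the unprotoplasted replicates, at 22.3 and 4.94 CPM, and had 4.88 and 2.71 without replicate 1 and replicate 2 of them. Photosynthesis genes rose in 3 of 9 and fell in 2 (0.742), with CA1 at 6.31, RBCS3B at 2.72 and PSBO1 at -2.71. The share of mitochondrial reads was 0.0441 and 0.0464% in protoplasted against 0.0135 and 0.0123% in unprotoplasted libraries.

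Adjusted over the list alone, the counts differed from those over all genes tested in 7 lists: 2 fallen genes for jasmonate, 2 for wall remodelling, 6 for cytokinin, 2 for root hair and 1 for cortex, and 6 risen genes for non-hair epidermis and 6 for root cap. The camera call of SHORT-ROOT downstream genes passed with no filter (0.0394) and without protoplasted replicate 1 (0.0455), in a range of 0.0394 to 0.342 over the alternatives. Without protoplasted replicate 1, cellulose synthesis (0.00676, range 0.00676 to 0.762) and cortex (0.0484, range 0.0484 to 0.386) passed too. Such a run leaves 1 library in that condition, so a p under 0.05 there is not stronger evidence. The fry test asks whether the members of a list move on balance to 1 side and compares them with no other genes. Its adjusted p is thus not a camera p. It was 0.028 for SHORT-ROOT downstream genes and 0.0277 for phloem, and under 0.05 for each list that passed camera. The direction of the test turned, without passing, for immune response (0.303, range 0.131 to 0.778) and photosynthesis (0.647, range 0.349 to 0.991) without unprotoplasted replicate 1, and for phloem (0.809, range 0.112 to 0.809) and photosynthesis (0.349) with the stricter filter. Leaving out each bulk library moved some named genes by more than 1.5-fold: SEOR2 ranged from -6.35 to -4.28, GPAT5 from -8.92 to -6.90, MLP328 from -11.03 to -8.58, TAT3 from 10.19 to 11.75 and ERF109 from 10.23 to 13.16. ADH1 was 4.76 at the lowest, CA1 7.06 at the highest, and ARR7 and PSBO1 were -3.49 and -3.55 at the lowest. With library size alone 5572 genes fell, the median of all genes shifted to -0.47, and the medians of the nitrate, root hair and photosynthesis lists turned from 0.36, 0.21 and 0.37 to -0.042, -0.19 and -0.030.

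The shr-3 library addresses what differs in root cells that lack SHR, a mobile transcription factor made in the stele that specifies the endodermis in the layer around it. The mutant has a mixed Col-0 and Ler background and wild type is Col-0. Effects of the background and of the loss of SHR cannot be told apart in these libraries. SHR transcripts (AT4G37650, chromosome 4, 17691687 to 17693859) were lower in shr-3 cells, at 3.15 CPM (95% exact Poisson interval 2.43 to 4.03) against 9.99 CPM in wild type (9.48 to 10.5), with 11.0 and 8.88 CPM in suffix 1 and suffix 2. SCR, the endodermal partner of SHR, was at 1.58 CPM (1.08 to 2.23) against 12.8 CPM (12.2 to 13.4), 7.99 times lower. The SHORT-ROOT downstream genes MGP, NUC and JKD, zinc finger genes, had log2 ratios of -2.53, -1.63 and -0.66, BR6OX2, of brassinosteroid synthesis, had -2.47 and SNE had -2.03. CYCD6;1, a cyclin gene of the cell division that forms cortex and endodermis, was higher at 3.99 against 2.61 CPM, a log2 ratio of 0.62 (0.25 to 0.96). SCL3 and MYB36, regulators of endodermal maturation, had log2 ratios of 0.68 and 0.56, which turned to -0.49 and -0.12 without cells over 4 times their library's median UMIs. The log2 ratio of SHR was -1.65 (-2.05 to -1.30) and -0.85 with every cell weighted alike. In wild type SHR was at 96.9 CPM in phloem-like and 55.5 CPM in xylem-like cells, and in shr-3 at 5.06 CPM (3 UMIs) and 26.5 CPM (29 UMIs), where both classes join 2 clusters in different proportions per genotype. With 1 shr-3 library no test across samples was made here, and the intervals cover counting error only.

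**Figure D2:**
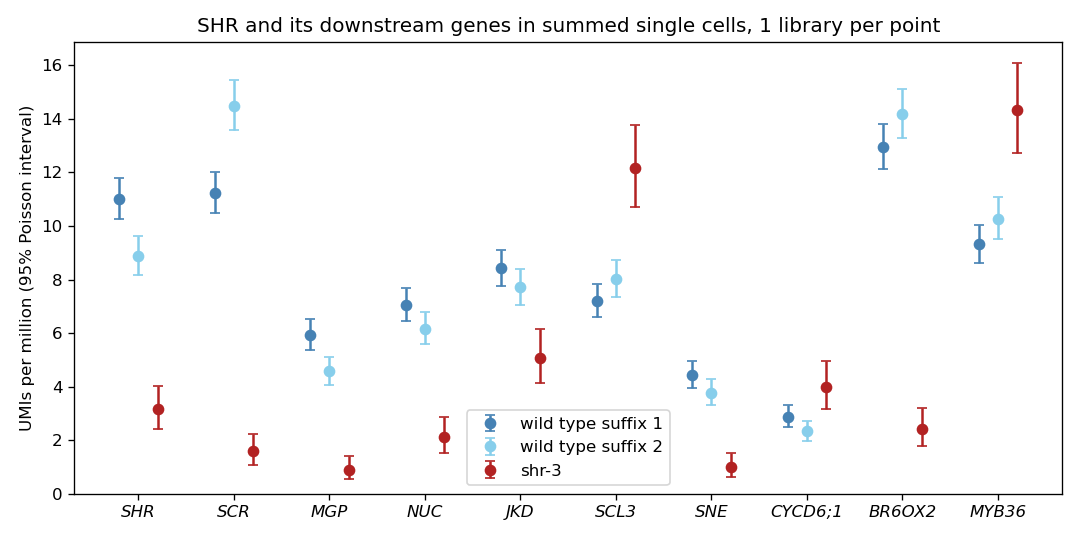
Level of SHR and its downstream genes in CPM of summed cells (linear axis) in wild-type suffix 1, wild-type suffix 2 and shr-3, with exact Poisson 95% intervals. SCR stands at 11.2, 14.5 and 1.58 CPM in these libraries.

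Across cell type lists, Casparian strip, suberin, vascular and root cap genes were higher in shr-3, and non-hair, cortex, DNA replication and mitosis genes were lower. The endodermis and Casparian strip list had a median log2 ratio of 4.52 (95% counting interval 4.40 to 4.64), above 100% of 10000 random lists matched on expression. CASP1 was at 186.1 against 2.85 CPM, CASP2 at 145.0 against 0.560 CPM, PER64 at 163.7 against 0.790 CPM and ESB1 at 225.4 against 5.36 CPM, while the members SCR and MGP were lower. The suberin list had a median of 3.69 (2.78 to 4.36), or 2.78 with genes at 0 UMIs set to their bounds, with GPAT5 at 4.24 against 0.0503 CPM and ASFT at 9.41 against 0.725 CPM. Phloem genes had a median of 2.67 (2.34 to 2.90), pericycle and procambium genes 2.47 (2.37 to 2.57), xylem genes 2.28 (2.18 to 2.37) and root cap genes 1.81 (1.73 to 1.89). SUC2, the phloem sucrose carrier, was at 69.5 against 6.73 CPM, APL at 35.9 against 4.14 CPM, XCP2, a xylem protease, at 275.1 against 61.5 CPM, TMO6 at 127.1 against 11.5 CPM and BRN1 at 131.1 against 31.8 CPM. Photosynthesis genes had a median of 9.65 (9.28 to 10.06), and 2.74 without the photosynthetic-like cells. Of the 10 highest ratios, RBCS2B and RBCS1B had 0 UMIs in wild type and were at least 5964-fold and at least 2587-fold higher. RBCS1A had 558.8 CPM in shr-3 and 2 UMIs in wild type, a log2 ratio of 14.93 (13.39 to 18.29), and RBCS3B, LHCA2 and LHCB1.1 had 12.23, 10.53 and 10.36. TGG1, FBA2, AT2G15780 and AT1G11925 completed these 10, with log2 ratios between 11.04 and 12.95 on 1 to 3 wild-type UMIs, and counting intervals from 9.71 to 18.84.

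Non-hair epidermis genes had a median log2 ratio of -2.56 (-2.94 to -2.26), DNA replication genes -2.23 (-2.29 to -1.84), mitosis genes -1.33 (-1.52 to -1.18) and cortex genes -1.32 (-1.81 to -0.96). The first 3 lay below all but 0.02% of matched random lists, and the cortex median below all but 1.51%. MYB23 and WER, which set the non-hair fate, were at 9.41 against 93.6 CPM and 7.24 against 54.4 CPM. PCNA1 was at 5.47 against 44.3 CPM and CDC20.1 at 1.92 against 13.0 CPM, while the histone genes HTR2 and HIS4 had log2 ratios of 0.45 and 1.07, so that the list's summed level was 896.6 against 815.3 CPM. HTR2 turned to -0.22 with every cell weighted alike. The cortex gene CO2 had 1 UMI in shr-3, a log2 ratio of -6.24 (-12.13 to -4.35), and AT5G02000 was at 0.838 against 14.2 CPM. Root hair genes had a median of -0.25 (-0.39 to -0.16), with RHD6 at -2.86 and LRX1 at 1.36, and niche genes -0.072 (-0.25 to 0.12), with RGF2 at -4.43 and PLT3 at 94.8 against 41.3 CPM. Both medians lay inside the range of random lists, above 26.3 and 47.3% of them. The 10 lowest ratios were those of RCI3, AGP30, AT4G11290, AT2G28790, GSTU14, ENODL15, ARP1, AT2G17080, AT3G15240 and FIB2, from -5.08 (-5.38 to -4.81) for RCI3, a peroxidase, to -3.33 for FIB2, fibrillarin. AGP30, a root arabinogalactan protein gene, was at 8.03 against 248.5 CPM.

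Among response lists, hypoxia genes had a median log2 ratio of 2.02 (1.77 to 2.25), osmotic stress and abscisic acid genes 1.88 (1.79 to 1.90), oxidative stress genes 1.14 (1.1 to 1.19), immune response genes 1.09 (0.75 to 1.28), early auxin response genes 0.85 (0.66 to 0.89) and jasmonate genes 0.71 (0.45 to 0.84). ADH1 was at 126.5 against 16.7 CPM, SUS1, a sucrose synthase, at 79.8 against 12.1 CPM, and ABI1, a phosphatase of abscisic acid signalling, at 411.8 against 93.0 CPM. COR47 was at 3749 against 984.6 CPM, OPR1 at 6287 against 1874 CPM, GSTU25 at 4388 against 1186 CPM and PEN3 at 116.3 against 34.1 CPM. IAA2 was at 255.2 against 136.4 CPM and IAA14 at 12.9 against 48.5 CPM, while MYC2 and ERF109 of the jasmonate list had log2 ratios of -0.83 and -0.79. Nitrate genes had a median of 0.70 (0.61 to 0.98), or 0.94 with bounds, with NRT1.1 at 118.1 against 28.8 CPM. Wall remodelling genes had 0.27 (0.19 to 0.65), iron uptake genes 0.22 (-0.39 to 0.28), or 1.04 with bounds, heat shock genes 0.10 (0.07 to 0.12) and early stress genes 0.060 (0.0031 to 0.0995). FIT was at 15.4 against 62.9 CPM, F6'H1, of coumarin synthesis, at 34.3 against 5.23 CPM, and XTH19 at 71.4 against 261.4 CPM. Cellulose synthesis genes had a median of -0.60 (-0.69 to -0.51), with COB at -0.99, and cytokinin response regulators -0.35 (-0.50 to -0.13), with ARR5 at -1.66. In the reported setting the medians of the hypoxia, osmotic, oxidative, immune and jasmonate lists lay above the 95% range of matched random lists. The other 8 lay inside it, above 95.8% of random lists for auxin, 76.8% for nitrate, 72.5% for wall remodelling, 68.7% for early stress, 67.9% for heat shock, 32.1% for iron, 19.7% for cytokinin and 13.4% for cellulose.

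Within classes of 1 cluster each these lists went both ways, and the summed values join such differences with the changed shares of the classes. In the 60 shr-3 and 30 wild-type endodermis-like cells, osmotic genes were at 22827 against 43232 CPM, jasmonate genes at 5309 against 14447 CPM and hypoxia genes at 288.8 against 616.2 CPM, while oxidative stress genes were at 26069 against 14934 CPM and immune genes at 853.2 against 696.5 CPM. In the 16 and 103 root hair-like cells, jasmonate genes were at 1822 against 4906 CPM, osmotic genes at 2774 against 4613 CPM, oxidative stress genes at 11861 against 13656 CPM and immune genes at 142.1 against 235.6 CPM, and hypoxia genes at 71.0 against 23.3 CPM. Root cap-like cells had 61260 against 49235 CPM of oxidative stress and 1692 against 5099 CPM of osmotic genes. Cortex-like cells, 17 and 141, had higher levels in shr-3 of all 5 lists, with osmotic genes at 5733 against 3069 CPM.

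Weighting every cell alike moved many list medians by more than 1.5 times. Among response lists it gave 0.15 for jasmonate, whose reported value stood just above the random limit of 0.679, 0.59 for oxidative stress, 0.64 for immune response, 0.61 for osmotic stress, 1.12 for hypoxia, 0.32 for nitrate, 0.70 for wall remodelling, -0.10 for cellulose and -0.12 for cytokinin. The auxin, iron and early stress lists turned to -0.039, -0.26 and -0.34. Among the others it gave -1.26 for DNA replication, -0.71 for mitosis, -1.30 for non-hair, 1.14 for xylem and 0.69 for root cap. Without cells over 4 times their library's median UMIs, a setting chosen after seeing the data, jasmonate was 0.36, osmotic stress 0.55, xylem 0.62, cytokinin -0.21 and early auxin -0.35. Against suffix 1 alone wall remodelling was 0.62, and against suffix 2 alone iron uptake was 0.035 and cytokinin -0.077. Over all settings the range was -0.58 to 0.23 for heat shock, -0.34 to 0.14 for early stress, -0.61 to 0.39 for iron uptake, 0.044 to 0.70 for wall remodelling, -0.59 to -0.12 for root hair and -0.55 to -0.012 for niche genes. Some medians outside the random range of the reported setting came inside it here. With every cell weighted alike these included jasmonate, oxidative stress (limit 0.651), immune response (0.847), root cap (1.16), mitosis (-0.787) and cortex (-0.94, limit -1.21). Without the cells of very high UMIs they included jasmonate, osmotic stress (0.587) and xylem (0.750). Against 1 suffix alone jasmonate reached 0.60 and cortex -1.15, also inside.

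Single genes moved as well. With every cell weighted alike the log2 ratio was 0.59 for OPR1 (reported 1.75), 0.63 for GSTU25 (1.89), 0.62 for COR47 (1.93), 1.14 for ABI1 (2.15), 1.83 for ADH1 (2.92), 1.70 for SUS1 (2.72) and 0.16 for IAA2 (0.90). It was 1.02 for XCP2 (2.16), 2.20 for TMO6 (3.47), 0.69 for BRN1 (2.04), 0.36 for PLT3, 0.60 for LRX1 (1.36), 0.67 for HIS4 (1.07), 0.36 for CYCD6;1 (0.62), 0.06 for SCL3 (0.68) and 1.00 for MYB36 (0.56). Negative values became -0.19 for COB (-0.99), -1.06 for ARR5 (-1.66), -2.09 for AT2G17080 (-3.38), -1.31 for ERF109 (-0.79), -2.67 for NUC (-1.63) and -1.34 for JKD (-0.66). Without the cells of very high UMIs COR47 was 0.48, XCP2 0.45, ABI1 1.35, IAA2 0.41, HTR2 0.10, LRX1 0.48, SUC2 2.23 (3.37), APL 1.23 (3.12), MGP -4.19, NUC -2.92 and JKD -1.71. Without photosynthetic-like cells the photosynthesis genes named above had lower ratios, with 2.74 for LHCB1.1, 3.52 for RBCS3B and 7.32 for RBCS1A, and TGG1 and FBA2 had 4.05 and 6.86.

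The cells of both genotypes were grouped together to compare the shares of cell classes, each named from fixed markers. Endodermis-like cells made up 5.46% of shr-3 cells (exact binomial 95% interval 4.19 to 6.97) and 0.635% of wild-type cells (0.429 to 0.905). An unnamed cluster of 50 suffix 1, 80 suffix 2 and 0 shr-3 cells had this as its best class, with a mean log2 fold of 0.635. Replicating-like cells made up 1.18% against 12.4%, mitotic-like cells 0.728% against 4.76%, niche-like cells 0.364% against 1.73% and non-hair-like cells 0.273% against 3.89%. Root cap-like cells made up 11.1% of shr-3 (9.30 to 13.1) and 1.95% of wild type (1.57 to 2.38). Photosynthetic-like cells made up 11.7% of shr-3 (9.89 to 13.8) and 0 of 4727 wild-type cells, which allows a share of up to 0.0635% at 3 counts of the total. Pericycle or procambium-like cells made up 9.01% of shr-3 and 0.0212% of wild type, where 1 cell fell in that class. The median was 4027 UMIs in the photosynthetic-like and 4623.5 in the pericycle or procambium-like cluster. The lowest wild-type cell held 6144 UMIs and the lowest shr-3 cell 2279, so different depth cutoffs may add to these differences. Among cells with at least 5000 UMIs, photosynthetic-like cells made up 6.09% of shr-3 and 0% of wild type. Xylem-like cells made up 6.01% against 4.44%, phloem-like cells 3.09% against 4.93% (clusters of 116, 105 and 18 and of 7, 5 and 16 cells from suffix 1, suffix 2 and shr-3), cortex-like cells 1.55% against 2.98% and root hair-like cells 1.46% against 2.18%. Suberised-like cells were 0 in both, which allows up to 0.0635% in wild type and 0.273% in shr-3. Unnamed cells made up 48.0% of shr-3 and 60.1% of wild type. In wild type, suffix 1 and suffix 2 held 0.380 and 0.890% endodermis-like, 13.6 and 11.1% replicating-like, and 6.04 and 3.47% mitotic-like cells.

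**Figure D3:**
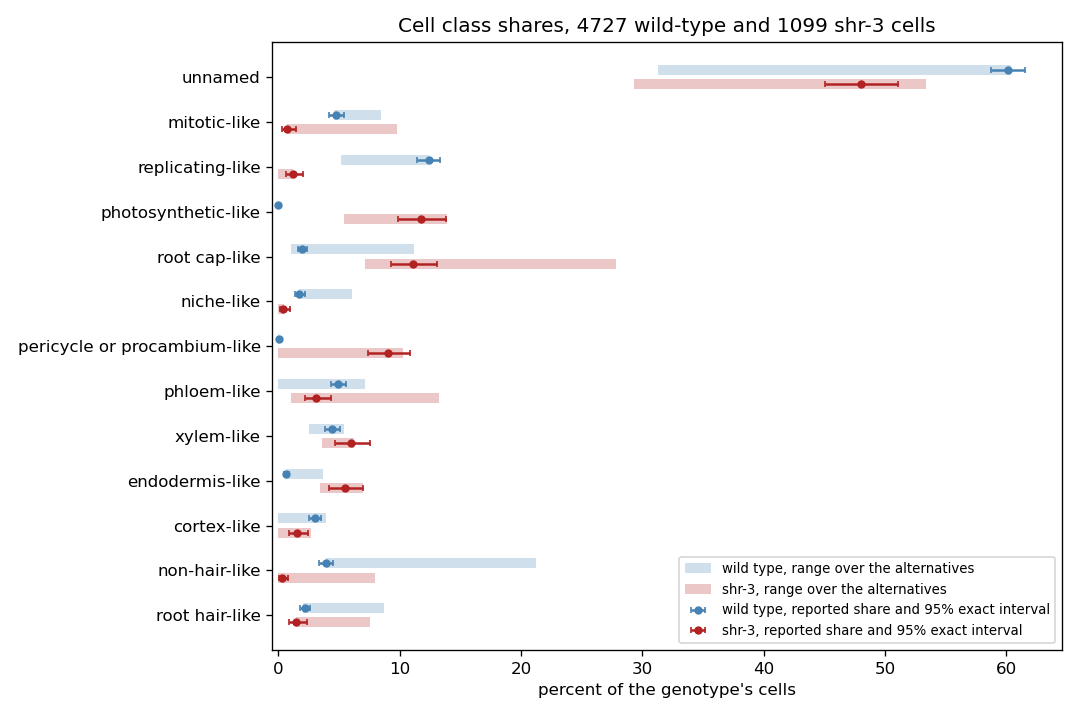
Share of each named cell class in percent of the cells of wild type and shr-3, with exact binomial 95% intervals and the range over the other settings. Replicating-like cells stand at 12.4% in wild type and 1.18% in shr-3.

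The order of the genotypes was the same in 9 of 9 settings for endodermis-like, root cap-like and photosynthetic-like cells, higher in shr-3, and for replicating-like, niche-like and non-hair-like cells, lower in shr-3. The reported replicating-like share of wild type was the highest of these settings, with a range of 5.16 to 12.4% in wild type and 0 to 1.18% in shr-3. Other ranges in wild type and shr-3 were 3.89 to 21.2% and 0 to 7.92% for non-hair-like, 1.73 to 6.09% and 0 to 0.455% for niche-like, 1.02 to 11.2% and 7.10 to 27.8% for root cap-like, and 0.635 to 3.68% and 3.42 to 7.01% for endodermis-like cells. Without genes 4-fold apart between the genotypes, a setting chosen after seeing the data, the shares in shr-3 and wild type were 5.55 and 3.41% for endodermis-like, 11.3 and 5.58% for root cap-like, 2.27 and 8.63% for non-hair-like, 9.55 and 2.43% for phloem-like, 1.91 and 6.07% for mitotic-like and 9.28 and 0.0212% for pericycle or procambium-like cells. Endodermis-like cells were 3.42 and 3.24% without cells over 4 times their library's median UMIs, and 5.46 and 3.38% with a marker score of 0.5, at which non-hair-like cells were 7.92 and 21.2%, root hair-like cells 4.64 and 8.74% and phloem-like cells 11.0 and 7.11%. Each genotype clustered alone turned the order of mitotic-like (9.74 and 6.47%), xylem-like (3.64 and 4.93%) and root hair-like cells (7.55 and 6.43%). Phloem-like cells were higher in shr-3 in 6 of 9 settings, cortex-like cells were lower in 7 and had no named cluster in the other 2, and no pericycle or procambium-like cells were named among cells with at least 5000 UMIs.

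Root hair-like cells of wild type, 103 in all, were ordered by diffusion pseudotime, since the series title names developmental trajectories. RHD6, which starts hair development, was at 139.9 CPM in part 1 of 5 of the order and 15.8 CPM in part 5, and ROPGEF3, which marks the site of the hair, at 159.5 and 37.5 CPM. COBL9 and RSL4, genes of hair outgrowth, had their highest level in part 3, with COBL9 at 483.2 CPM, and LRX1, CSLD3 and RBOHC in part 2, with LRX1 at 665.3 CPM. RSL2, a further gene of hair outgrowth with 516 UMIs in all, changed little, from 176.9 CPM in part 4 to 222.9 CPM in part 3. PRP3, a wall protein gene, was at 1912 CPM in part 1 and 4715 CPM in part 5, ADF8 at 1124 and 2982 CPM and RHS19 at 845.5 and 2083 CPM. ADF8 was lower in part 2, at 975.1 CPM, and RHS19 in parts 2 and 3, at 638.4 and 437.8 CPM, so neither rose throughout. The DNA replication list that set the direction was at 52.8, 53.9, 78.9, 57.4 and 21.7 CPM over the 5 parts of 20 or 21 cells, so the start is weakly fixed. With a marker score of 0.5 the order covered 413 cells, and 5 of 20 markers had their highest level in the part of the same number. The root hair list went from 625.9 CPM in part 1 to 9231 CPM in part 5 of that order. Its parts are thus not the same stretches as those of the 103 cells, and the count of 5 says little about the reported order. In the order of 413 cells RHD6 did not decline, with 59.7 CPM in part 1, its highest level of 123.4 CPM in part 4 and 68.6 CPM in part 5. The DNA replication list went from 209.5 CPM in part 1 to 1168 CPM in part 5 there.

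Summed wild-type cells were compared with each bulk library across 27628 genes, as log2(CPM + 1). Pearson's r was 0.894 and 0.905 with protoplasted replicates 1 and 2, and 0.851 and 0.849 with unprotoplasted replicates 1 and 2, and Spearman's rho was 0.911, 0.918, 0.873 and 0.871. Genes are not independent replicates, so no p is given. The wild-type suffixes correlated at r = 0.997, with 76 of 4496 genes at least 2-fold apart, and shr-3 with suffix 1 and suffix 2 at 0.908 and 0.921, with 2482 and 2257 genes apart.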

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

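Transcripts of GFP, a feature that no comparison of gene lists uses, numbered 126 UMIs in 52 of the 2360 wild-type cells of suffix 2. Suffix 1 had 0 GFP UMIs in 2367 cells and shr-3 had 0 in 1099 cells. This stood out because a signal appears in a feature outside the comparisons, above the level of the libraries without it. The labels give the endodermal reporter to wild-type replicate 2 and do not say which suffix that replicate carries. GFP in suffix 2 alone argues against suffix 1 as the reporter library. No other explanation was tested.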

How the results depend on the processing

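Most results kept their direction and their side of the threshold, and the cause of the changes given here was not tested unless stated. Without composition factors 5572 bulk genes fell in place of 3062, since library size alone shifts all genes downward by construction. The count of risen genes stayed within 1.5 times the reported one in each alternative run, from 2794 with the stricter filter, where fewer genes were tested, to 4110 with no filter. Leaving out each bulk library gave 3668 to 3802 risen and 2650 to 3173 fallen genes, and replicate number as a block (replicate block) gave 3648 and 3014. Between 0 and 10 of the 123 named bulk genes lost their call in an alternative: 4 with DESeq2, 2 with its size factors, 2 with library size alone, 2 with the replicate block, 0 with limma-voom, 3 without protoplasted replicate 2, and 10 and 7 without unprotoplasted replicates 1 and 2. With the filter of 1 CPM in all 4 libraries, 86 of these genes had the same call and 1 gained one. The rest were not tested there, CYP86A1 among them. For single genes in shr-3 against wild type, a change of sign was counted as a turn only where the reported counting interval excluded 0. PRP3 went from -0.007 to as high as 0.16 and was not counted. Of 151 such genes, 99 moved beyond counting error without a counted turn with every cell weighted alike. The number was 94 without the cells of very high UMIs, and 67 and 64 against suffix 2 and suffix 1 alone. It was 43 in cells with at least 5000 UMIs, 36 with a TMM factor and 22 without photosynthetic-like cells. A turn was counted for 9 with every cell weighted alike and 9 without the cells of very high UMIs. It was counted for 1 in cells with at least 5000 UMIs, 1 against suffix 1 alone and 1 without photosynthetic-like cells. The pseudocount and filter planned for normalized bulk values were not run, because the values are counts. The shr-3 library held 20294416 UMIs, and levels under 3 counts are not read as absence. Settings without photosynthetic-like cells, without cells of very high UMIs, without genes 4-fold apart and with the score of 0.5 were chosen after seeing the data.

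Among bulk lists, the camera adjusted p with an estimated correlation was 0.22 for jasmonate and early stress, 0.255 for heat shock, hypoxia, wall remodelling, auxin, mitosis, endodermis, suberin, pericycle and root cap and 0.332 for oxidative stress. It was 0.36 for osmotic stress and xylem, 0.386 for cytokinin, 0.311 for iron uptake, 0.368 for DNA replication and 0.287 for non-hair. In this setting 18 of 18 calls were lost. It rests on the few residual degrees of freedom of 4 libraries, so the loss does not show that correlation among genes undoes the calls. The adjusted p was 0.0948 for cytokinin, 0.239 for iron uptake, 0.809 for phloem and 0.349 for photosynthesis with the filter of 1 CPM in all 4 libraries, where fewer genes were tested and the direction of phloem and photosynthesis turned. It was 0.0394 for SHORT-ROOT downstream with no filter. With fry, which compares a list with no other genes, the adjusted p was 0.028 for SHORT-ROOT downstream and 0.0277 for phloem. It was under 0.05 for all 18 lists that passed camera. Leaving out each bulk library in turn gave adjusted p values of 0.232 to 0.431 for immune response, 0.00676 to 0.688 for cellulose synthesis, 0.0163 to 0.0883 for cytokinin, 0.0455 to 0.131 for SHORT-ROOT downstream, 0.0301 to 0.112 for non-hair, 0.0484 to 0.264 for cortex and 0.646 to 0.991 for photosynthesis. Where this left an arm with 1 library, that library was assumed to vary like the other group.

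Taking each wild-type suffix alone as the reference gave log2 ratios of 0.046 to 0.16 for heat shock, -0.015 to 0.14 for early stress, 1.1 to 1.27 for oxidative stress, 1.65 to 1.99 for osmotic stress, 0.91 to 1.44 for immune response, 0.8 to 0.9 for auxin and -0.48 to -0.077 for cytokinin. The further ranges were -1.69 to -0.95 for mitosis, -0.41 to -0.12 for root hair and 2.1 to 2.35 for xylem, and -0.44 to 0.018 for NIR1, 0.26 to 0.62 for wall remodelling and 0.035 to 0.26 for iron uptake. A TMM factor between the genotypes gave log2 ratios of 0.026 for heat shock, -0.014 for early stress, 1.07 for oxidative stress, 0.19 for wall remodelling and -2.3 for DNA replication. Weighting every cell alike gave log2 ratios of 0.15 for jasmonate, 0.23 for heat shock, -0.34 for early stress, 0.59 for oxidative stress, 0.61 for osmotic stress, 0.64 for immune response, 1.12 for hypoxia, -0.1 for cellulose synthesis and 0.7 for wall remodelling. It further gave -0.039 for auxin, -0.12 for cytokinin, 0.32 for nitrate, -1.26 for DNA replication, -0.71 for mitosis, -2.1 for SHORT-ROOT downstream, -0.44 for root hair, -1.3 for non-hair and -0.94 for cortex. It also gave 4.93 for endodermis, 4.7 for suberin, 1.14 for xylem, 2.33 for phloem, 1.72 for pericycle, -0.55 for niche, 0.69 for root cap, 11.96 for photosynthesis and -0.85 for SHR. Beyond these it gave -0.34 for JAZ1, 0.23 for HSP17.6A, -0.33 for ERD10, -0.17 for RD29A, -0.2 for PROPEP3, -0.054 for IAA19, 0.32 for NIR1, -0.22 for HTR2 and -0.088 for CVIF2. Keeping cells with at least 5000 UMIs gave log2 ratios of 0.053 for heat shock, 1.2 for oxidative stress, 1.93 for osmotic stress, -0.72 for cellulose synthesis, 0.044 for wall remodelling, -1.54 for mitosis, 4.24 for endodermis, 2.09 for phloem and 8.42 for photosynthesis. It further gave -0.018 for CTL1. Keeping list members with at least 10 UMIs gave log2 ratios of -0.61 for iron uptake and 2.13 for pericycle. Leaving out photosynthetic-like cells gave log2 ratios of -0.093 for heat shock, -0.00021 for early stress, -1.85 for cortex, 2.33 for phloem, 2.74 for photosynthesis and -0.093 for MBF1C. Leaving out cells over 4 times their library's median UMIs gave log2 ratios of 0.36 for jasmonate, -0.58 for heat shock, -0.34 for early stress, 1.03 for oxidative stress, 0.55 for osmotic stress, 1.35 for hypoxia, -0.35 for auxin, 0.39 for iron uptake and -1.54 for DNA replication. It further gave -0.59 for root hair, -2.23 for non-hair, 4.03 for endodermis, 0.62 for xylem, 2.17 for phloem, 2.13 for pericycle, -0.33 for niche, 1.39 for root cap and 10.64 for photosynthesis. It also gave -0.49 for SCL3, -0.12 for MYB36, -0.25 for JAZ1, -0.023 for MBF1C, -0.42 for HSP17.6II, -0.25 for ERD10, -0.77 for RD29A, -0.3 for PROPEP3 and -0.9 for CVIF2.

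The shares here are in percent of cells. Leiden resolution 0.5 gave wild-type shares of 11.1 non-hair-like, 0 cortex-like, 3.64 endodermis-like, 4 phloem-like, 11.2 root cap-like, 7.85 replicating-like, 5.94 mitotic-like and 47.7 unnamed. In shr-3 the shares were 1 non-hair-like, 0 cortex-like, 7.01 endodermis-like, 27.8 root cap-like and 30.8 unnamed. Leiden resolution 2 gave wild-type shares of 6.92 non-hair-like, 2.54 xylem-like, 1.97 phloem-like, 6.09 niche-like, 3.07 root cap-like and 8.57 replicating-like. Those of shr-3 were 3.55 xylem-like, 8.19 root cap-like and 53.4 unnamed. Clustering without the genes changed by protoplasting gave wild-type shares of 5.5 root hair-like, 10.3 non-hair-like, 0 cortex-like, 3.68 endodermis-like, 3.77 xylem-like, 2.98 phloem-like, 3.17 niche-like, 1.02 root cap-like, 6.11 replicating-like, 8.42 mitotic-like and 55 unnamed. For shr-3 it gave 3.28 root hair-like, 4.19 non-hair-like, 0 cortex-like, 4.37 phloem-like, 17.7 root cap-like and 34.8 unnamed. Clustering each genotype alone gave wild-type shares of 6.43 root hair-like, 6.79 non-hair-like, 3.96 cortex-like, 2.88 endodermis-like, 0 phloem-like, 0 pericycle-like, 3.68 niche-like, 4.17 root cap-like, 5.42 replicating-like, 6.47 mitotic-like and 55.3 unnamed. The shr-3 shares became 7.55 root hair-like, 0 non-hair-like, 0 cortex-like, 3.64 xylem-like, 1 phloem-like, 0 niche-like, 7.1 root cap-like, 5.37 photosynthetic-like, 0 replicating-like and 9.74 mitotic-like. Cells with at least 5000 UMIs gave wild-type shares of 6.41 root hair-like, 6.03 non-hair-like, 3.45 endodermis-like, 2.41 phloem-like, 0 pericycle-like, 3.24 niche-like, 5.97 root cap-like, 5.16 replicating-like and 54.9 unnamed. In the mutant they were 5.26 root hair-like, 13.2 phloem-like, 0 pericycle-like, 23 root cap-like, 6.09 photosynthetic-like and 35.7 unnamed. The marker score of 0.5 gave wild-type shares of 8.74 root hair-like, 21.2 non-hair-like, 3.38 endodermis-like, 7.11 phloem-like and 31.3 unnamed. Among shr-3 cells the shares were 4.64 root hair-like, 7.92 non-hair-like, 11 phloem-like and 29.3 unnamed. Clustering without genes 4-fold apart between the genotypes gave wild-type shares of 8.63 non-hair-like, 3.41 endodermis-like, 3.13 xylem-like, 2.43 phloem-like, 3.98 niche-like, 5.58 root cap-like, 6.11 replicating-like, 6.07 mitotic-like and 55.5 unnamed. Shares in shr-3 were 2.27 non-hair-like, 4.28 xylem-like, 9.55 phloem-like, 1.91 mitotic-like and 39.9 unnamed. Clustering without cells over 4 times their library's median UMIs gave wild-type shares of 9.41 non-hair-like, 3.24 endodermis-like, 5.37 xylem-like, 3.22 niche-like, 1.55 root cap-like, 7.09 replicating-like, 5.71 mitotic-like and 53.2 unnamed. The mutant had 1.07 non-hair-like, 2.67 cortex-like, 3.42 endodermis-like, 14.4 root cap-like, 13.9 photosynthetic-like and 41.5 unnamed.

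With the score of 0.5, 5 of 20 root hair markers peaked in the part of the same number, but the parts of that larger order hold other stretches of cells. The rank correlation with the reported root hair order was 0.977 with 30 neighbours and 0.9996 without the root hair, DNA replication and mitosis lists. Pearson's r with protoplasted replicates 1 and 2 and unprotoplasted replicates 1 and 2 was 0.914, 0.921, 0.878 and 0.876 with a pseudocount of 0.1, and 0.765, 0.787, 0.715 and 0.709 over genes with at least 1 CPM in both.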

Other observations

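The tests of the 3 patterns weighed here were chosen only after the results were seen. Stress and hormone gene lists had different levels among the wild-type cell classes, in summed CPM of each list. Oxidative stress and detoxification genes were at 49235 CPM in root cap-like cells against 4839 CPM in xylem-like cells. Osmotic stress and abscisic acid genes were at 43232 CPM in the 30 endodermis-like cells and 16469 CPM in niche-like cells, against 1233 CPM in mitotic-like cells. Heat shock genes were at 12722 CPM in niche-like and 2489 CPM in root hair-like cells. Early auxin response genes were at 2174 CPM in xylem-like and 106.4 CPM in mitotic-like cells. Iron uptake genes were at 998.6 CPM in root hair-like and 692.2 CPM in cortex-like cells, against 85.6 CPM in xylem-like cells, and nitrate genes at 538.0 CPM in root hair-like and 58.8 CPM in xylem-like cells. Cellulose synthesis genes were at 3749 CPM in cortex-like and 332.3 CPM in mitotic-like cells, and cytokinin response regulators at 671.3 CPM in niche-like and 116.5 CPM in mitotic-like cells. SCR was at 33.5 CPM in replicating-like, 29.7 CPM in endodermis-like and 26.7 CPM in mitotic-like cells.

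Several unnamed clusters had distinct leading genes. A cluster of 96 cells, from suffix 1, suffix 2 and shr-3 with 44, 40 and 12 cells, was led by WRKY30 and PER4 and held WRKY53, WRKY41 and PROPEP3 among its top 10 genes. A cluster of 268 cells was led by the chaperone genes HSP21 and HSP22.0, with 11 cells from shr-3. A cluster of 205 cells was led by genes of the mitochondrial and plastid genomes. A cluster of 130 cells, with 50 cells of suffix 1, 80 of suffix 2 and 0 of shr-3, was led by the peroxidase genes RCI3 and AT4G11290 and held MYB68. Its best class was endodermis-like, with 5 markers raised and a mean log2 fold of 0.635, and it is one of the clusters named at a score of 0.5. In shr-3, heat shock genes were at 26871 CPM in photosynthetic-like cells and 1285 CPM in pericycle or procambium-like cells.

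Photosynthesis genes were high in the shr-3 library and near 0 in wild type. The 129 photosynthetic-like cells held 98.8% of the list's shr-3 UMIs and 3.20% of all shr-3 UMIs, which argues against free RNA spread over the library. Shoot cells in the sample are a candidate source, and root cells that turned green are another. At most 2 markers of any root cell type were raised in these cells, and no fixed marker list separates the readings, so both stay open. All of these cells come from 1 library, so an effect of that library, of its mixed Col-0 and Ler background or of the mutation cannot be told apart. In the reported clusters their median was 4027 UMIs, below the lowest wild-type cell at 6144, so different depth cutoffs may add to the difference.

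Casparian strip genes were higher in shr-3 although SHR and SCR were lower. Wild-type cells like those measured here would bring the list to the wild-type level at most. The list's total was 19.6 times that level, at 913.9 against 46.6 CPM (41.5 and 52.2 in suffix 1 and suffix 2). This follows from the rise itself, so it is no separate test of that explanation. A larger share of endodermis-like cells stays open: within them the list's members outside the SHORT-ROOT list were at 10.5 times the wild-type level (60 against 30 cells), but the class is named from markers of this list and its wild-type share ranged from 0.635 to 3.68% with the setting. The shr-3 sample might hold an older stretch of root, and its mitosis list was at 0.371 of the wild-type level. The mutation, its mixed Col-0 and Ler background and the stretch of root are confounded in 1 library. An older stretch, the background and a biological effect of shr-3 thus stay open.

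Suberin genes were near 0 in protoplasted bulk roots. Loss of endodermal cells as a whole is argued against, since the suberin member that fell least was at a log2 fold of -3.09 and the Casparian strip member that fell most was at -1.66. Scaling of the libraries is argued against too, with -3.02 as the highest suberin value under the scalings tried. Suberised cells or an older stretch of root may be missing from the protoplasts, or these transcripts may be lost during digestion. Summed wild-type cells held 0.991 CPM of the list, which goes with either reading and leaves both open.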
